A study of Rattus norvegicus with 6 samples.

How the data were processed

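RNA was measured in 6 libraries of rat spinal cord, 3 from a spinal cord injury model with electrical stimulation (ES) and 3 from the model without it (SCI). Per the labels' protocols, poly(A) RNA was selected from 1 ug of total RNA and made into stranded paired-end libraries with inserts near 300 bp. Samples were put into groups by their treatment labels, and the columns of the tables were matched to samples by treatment and replicate number.

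The authors deposited FPKM values per library for 32623 genes and 40808 transcripts. FPKM is the number of fragments per kilobase of feature, scaled to the library's number of fragments, and the authors wrote 0.0001 in place of 0. HISAT and StringTie are named in the submitters' processing notes, with neither version nor role. The genome build, the annotation release and the aligner settings are not given in the sources used here, so coordinates are as the files give them. The authors' fold column is, from the values, the ratio of the mean FPKM in ES to the mean in SCI, and their log2 column is its log2, per the file headers. The authors also deposited a p-value and a q-value per feature, from a test that is not given in the sources used here. The features the authors marked as significant are those with a p-value under 0.05 and a log2 change of at least 1 in size. Gene symbols came from the tables, and 19110 of them were found in a reference gene table of assembly GRCr8, which was used for names only. In the tables used here 1951 cells of GO terms and 1 of KEGG terms were left out.

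Because the values are FPKM and not whole-number reads, no model for read numbers was used. Genes and transcripts with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided. Adjusted p-values are Benjamini-Hochberg values over all features tested, and a call needs an adjusted p under 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and fold values of genes in the text are ratios of mean FPKM. The fold minimums among the alternatives are on the log2(FPKM + 1) scale. Depth was estimated from the smallest steps of low transcript values, which assumes that 1 step is 1 read pair. It gave 13900000 to 18600000 read pairs per library, so that fragment sampling alone gives a coefficient of variation of about 2.64% to 2.82% at 30 to 100 FPKM. The median variance between 3 libraries lies below the expected one, so its ratio to sampling was divided by the median of a chi-square with 2 degrees of freedom over 2.

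Gene lists were tested with camera of limma with a preset correlation of 0.01, over 39 lists with 776 entries that were fixed before the data were examined and needed at least 5 tested members. Annotation terms with 15 to 300 tested genes were tested in the same way. Beside each list stands the number of members called over all genes and adjusted over the list alone. Transcript usage was tested with diffSplice of limma and a Simes p per gene, over genes with at least 2 transcripts past the filter. Shares of a transcript are its FPKM over the sum of the gene's transcripts in the same library.

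The rule for named genes was also fixed before the data were examined. It took the 12 genes with the largest change in each direction among called genes with a symbol, at least 1 FPKM in a group and no overlap between groups, leaving out ribosomal and mitochondrially encoded genes. It also took up to 4 members of each list by smallest p, 3 transcripts in each direction and 5 usage genes by smallest p, and the 5 genes in each direction with the smallest p in the authors' deposited table. List members named beyond the first 4 are those that went against their list, those that did not pass, or those set beside a family member, and they were chosen after their values were seen. Some genes that the rule takes are not reported here.

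Alternatives chosen in advance were pseudocounts of 0.1 and 0.01, no filter or a filter of 2 FPKM, quantile normalization, rescaling to equal totals, median centring, array quality weights, no trend, leaving out each library in turn, the replicate number as a block, an adjusted p under 0.1, and a 2-fold minimum. For lists and terms a correlation estimated from the data was run, and for lists also the rotation test fry. Alternatives added after the values were seen were a 1.5-fold minimum, leaving out genes whose libraries lay more than 2-fold apart within a group at a mean of 2 FPKM or more, and, for lists, median centring and rescaling to equal totals.

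The tests were tried on simulated data before use. In the simulated gene comparison of 15764 genes, 77.6% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 100% of 66 changed 4-fold were recovered, with 14 false calls among 194. In the simulated list comparison 1 of 1 changed list and 1 of 200 random lists were called. In the simulated transcript comparison of 19205 transcripts, 100% of 100 transcripts changed 3-fold were recovered with 9 false calls. In the simulated usage comparison of 2582 genes, 100% of 100 changed genes were recovered with 8 false calls. Features were simulated independently of each other, with the same small extra spread at every level. The observed extra spread was larger in low genes, at 10.0% in SCI at 1 to 3 FPKM against 2.22% at 300 FPKM and above. The list result therefore cannot show how the preset correlation behaves for correlated genes, and recovery of low genes may be lower than simulated. In the gene simulation only a small share of genes was changed, as many raised as lowered, with no shift in scaling between groups. Its recovery and false calls therefore do not describe data in which 45% of the genes tested were called. Values were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.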

Results

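Bulk poly(A) RNA was sequenced from the spinal cord of female Wistar rats of a spinal cord injury model. 3 libraries came from animals given electrical stimulation (ES) and 3 from injured animals without it (SCI). The question was which genes, transcripts and gene groups differ in injured cord with stimulation. The tables gave FPKM (fragments per kilobase, scaled to library size) for 32623 genes and 40808 transcripts. Between 18878 and 19239 genes per library had a value above 0, and between 14134 and 14515 reached 1 FPKM. From the smallest steps in the transcript values, taking 1 step as 1 read pair, the depth was estimated, to 3 digits, at 13900000, 15100000 and 16100000 read pairs in ES replicates 1 to 3. The same estimate gave 16300000, 16500000 and 18600000 in SCI. Correlations of log2(FPKM + 1) lay between 0.984 and 0.986 within groups and between 0.962 and 0.965 across groups. At 30 to 100 FPKM the median coefficient of variation between libraries was 2.81% in ES and 3.41% in SCI. The variance there, corrected for the use of a median over 3 libraries, was 1.54 times that of fragment sampling alone in ES and 2.49 times in SCI, and 3.46 and 8.57 times at 300 FPKM and above. The labels do not say that each library is a separate rat, so the p-values measure only the spread between these libraries, which may be technical.

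Red cell and granulocyte genes were among the genes that rose most with stimulation. Hbb, a beta-globin chain (chromosome 1, 168971274 to 168972725 in the files' coordinates), reached 720 ± 8.78 FPKM in ES against 106 ± 1.60 in SCI (SD, n = 3), a 6.77-fold difference (log2 fold change 2.75 ± 0.02 SE, adjusted p = 3.90e-08). S100a8, a calcium-binding protein abundant in neutrophils, was 6.72-fold higher (21.8 ± 2.03 against 3.24 ± 0.481 FPKM), and the chemokine Ccl6 4.89-fold (58.4 ± 2.87 against 11.9 ± 0.155). Igf2, a fetal growth factor also made by meninges and vessels, fell from 253 ± 26.3 FPKM in SCI to 43.3 ± 0.798 in ES (log2 fold change -2.51 ± 0.07, adjusted p = 2.78e-06). Thbs1, the matrix protein thrombospondin 1, fell from 50.8 ± 0.593 to 6.66 ± 0.308 FPKM (log2 fold change -2.76 ± 0.04, adjusted p = 2.77e-07).

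Among the 12 genes with the largest positive change, Hba-a1, Hba-a2 and Hbb-bs, further globin chains, rose 5.52-fold, 5.41-fold and 5.67-fold. Ifit1, an interferon-induced RNA-binding protein (chromosome 1, 252944103 to 252946170), rose from 0.206 ± 0.104 to 9.14 ± 0.680 FPKM, 44.3-fold. Pnlip, pancreatic triacylglycerol lipase, rose 7.89-fold to 52.8 ± 0.859 FPKM. Igfbp3, which binds insulin-like growth factors, rose 5.10-fold to 133 ± 2.00 FPKM. Slpi, a leukocyte protease inhibitor, rose 9.48-fold to 8.31 ± 0.436 FPKM. The defensin genes Defa5 and Np4 were listed at 0 in the 3 SCI libraries. In ES replicates 1 to 3 they stood at 4.45, 6.89 and 5.29 FPKM and at 3.87, 3.98 and 4.07 FPKM. Globin, defensin, Ifit and RT1 genes have near-identical copies among which reads can be divided, so the value of each single copy is uncertain.

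Among the 12 with the largest negative change, the keratin genes Krt19 and Krt75 fell to 0.322 ± 0.183 and 0.533 ± 0.0485 FPKM from 10.1 ± 0.126 and 7.73 ± 1.14. Shisa3 fell from 22.6 ± 1.54 to 1.80 ± 0.0744 FPKM, and the matricellular gene Ccn3 from 44.6 ± 0.394 to 8.86 ± 0.343. Pdgfrl, Clec11a, a secreted growth factor of bone and marrow, and Slc26a7, an anion exchanger, fell to 5.95 ± 0.461, 2.47 ± 0.404 and 0.893 ± 0.105 FPKM from 27.5 ± 1.44, 13.2 ± 0.571 and 7.15 ± 0.475. RT1-M2, a class Ib histocompatibility gene, fell from 7.14 ± 0.836 to 0.317 ± 0.117 FPKM. Aqp4, the water channel of astrocyte endfeet, stood at 26.1, 134 and 29.2 FPKM in ES replicates 1 to 3 against 295 ± 11.5 in SCI. Its log2 fold change was -2.62 (adjusted p = 0.0113) and -3.37 without ES replicate 2. Zmiz2 was listed at 0 in ES replicates 1 and 3 and at 2.46 FPKM in ES replicate 2, against 9.45 ± 0.463 in SCI. Its log2 fold change was -2.79 (adjusted p = 0.00356) and -3.38 without ES replicate 2.

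**Figure D1:**
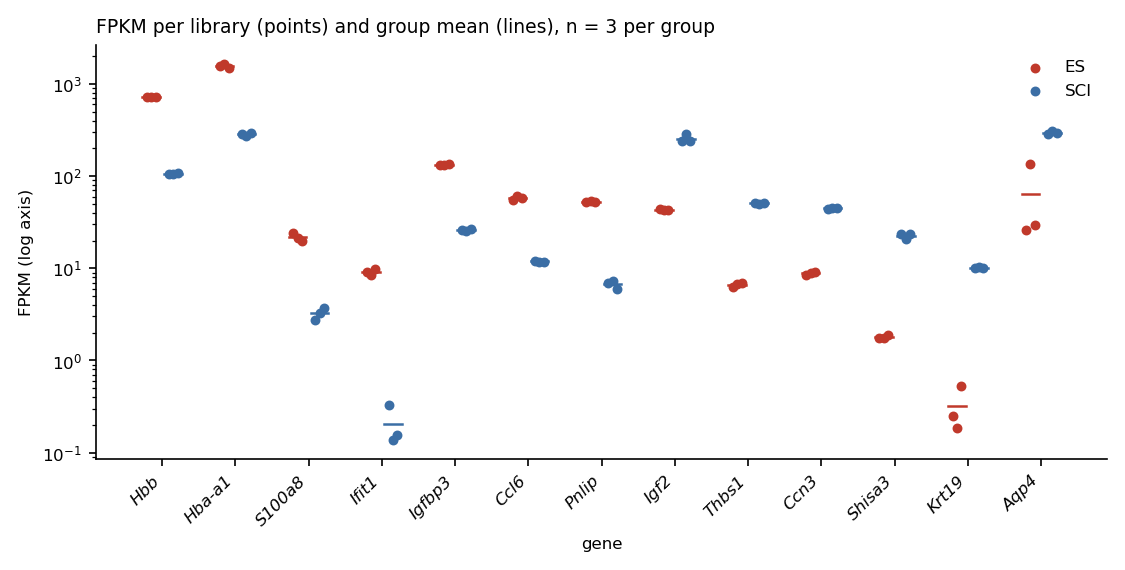
FPKM of 13 named genes on a log axis. Points are libraries (3 ES in red, 3 SCI in blue) and lines are group means. The groups do not overlap for any gene shown, and Aqp4 in ES spreads from 26.1 to 134 FPKM.

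In the test over all genes, 15750 passed the filter and 7088 of them (45%) differed, 2747 higher and 4341 lower in ES. On the log2(FPKM + 1) scale a change of at least 1 in size was reached by 136 of the higher and 288 of the lower genes. The median log2 change was 0.34 among the higher genes, -0.40 among the lower ones and -0.06 over all genes tested. The split of the calls rested on the scaling. It was 3414 higher and 3257 lower after quantile normalization, 3347 and 3575 after median centring, and 2078 and 5642 after rescaling to equal totals. The authors' deposited table marked 1026 genes as significant, 274 up and 752 down. Of these, 863 were called here in the same direction and 0 in the opposite one, 37 were tested and not called, and 126 lay below the filter. The smallest p-values in the authors' deposited table belonged to Hbb, Igfbp3, Hba-a1, Hba-a2 and Hbb-bs among higher genes, and to Thbs1, Igf2, Ccn3, Prx and Shisa3 among lower ones. Prx, a protein of Schwann cell myelin, had a log2 fold change of -1.62 in the authors' deposited table.

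As groups, red cell and myelin genes rose with stimulation, with median log2 fold changes of 2.18 and 0.55, and interferon response genes fell, with a median of -0.78. The median of cell cycle genes was 0.59, and Schwann cell, vessel wall and astrocyte genes had medians of -0.69, -0.51 and -0.48. These groups are among 39 lists fixed in advance. The test was camera with a preset correlation, run over all lists, and 23 lists passed it, 15 towards higher and 8 towards lower values in ES. With a correlation estimated from the data 3 of these held, the erythrocyte, the oligodendrocyte and the interferon lists. Library shares moved with the groups as well. Mitochondrially encoded genes took 15.3% to 15.5% of all gene FPKM in ES and 11.1% to 12.1% in SCI. Within these shares Mt-atp6 alone took 2.63% to 2.72% and 0.494% to 0.561%. It overlaps Mt-atp8, so its share may depend on how reads were divided between them. Leaving out genes whose libraries lay more than 2-fold apart within a group, an alternative added after the values were seen, left 23 lists past the threshold.

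**Figure D2:**
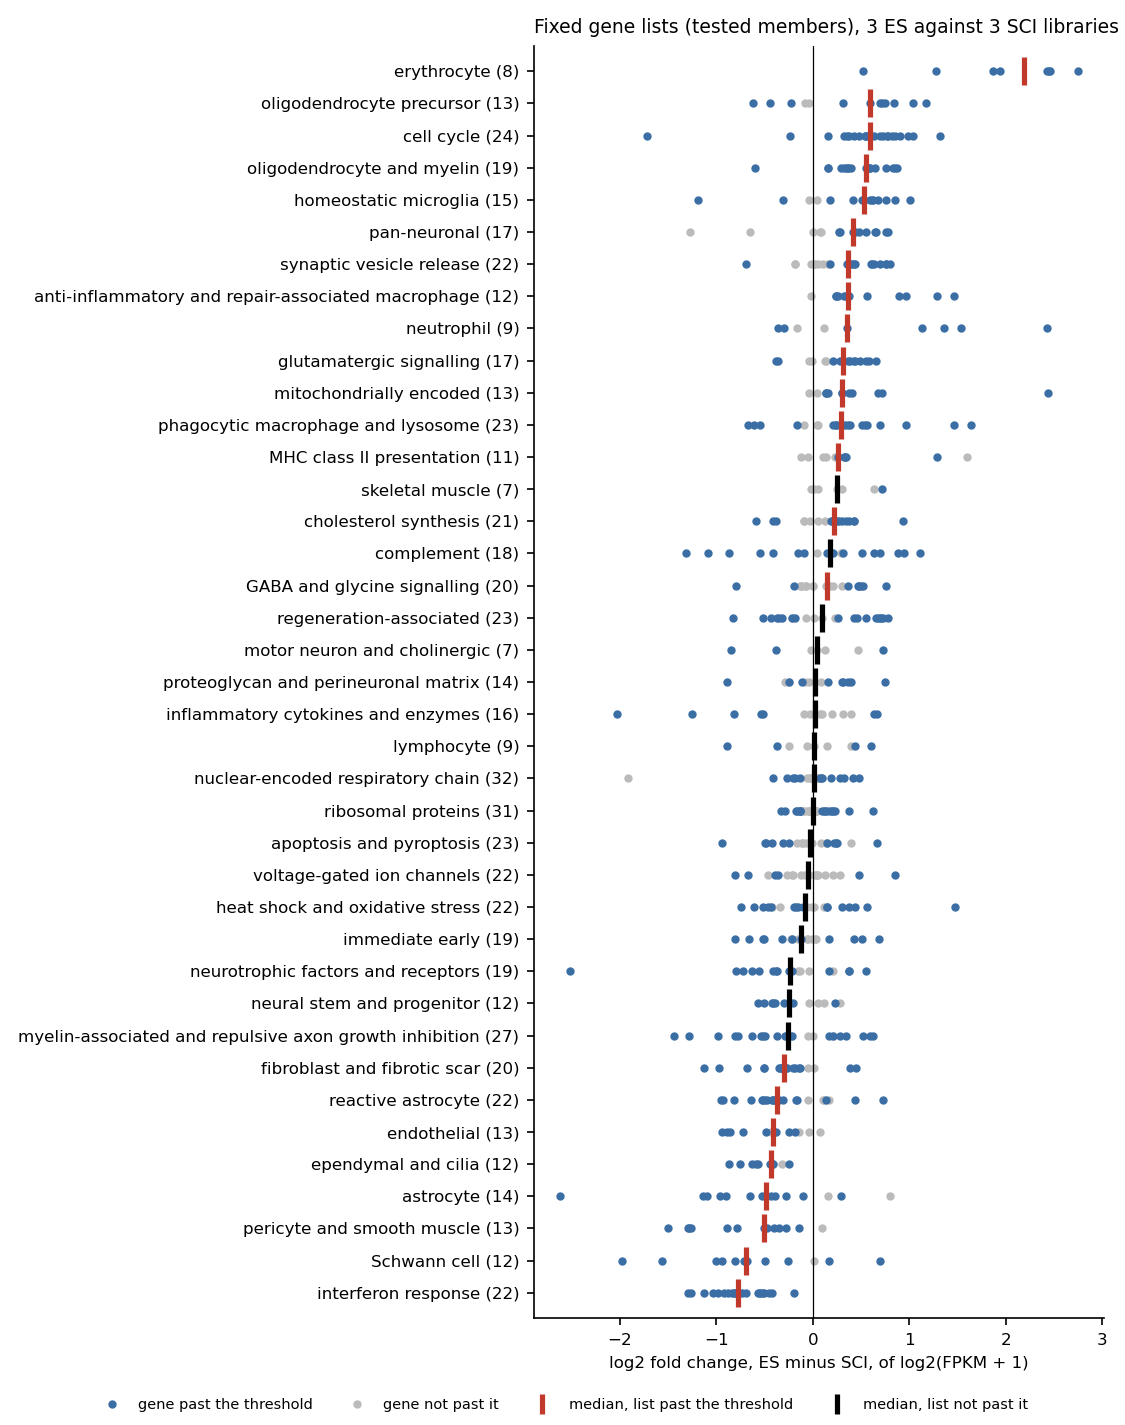
Log2 fold changes (ES minus SCI, of FPKM + 1) of the tested members of the 39 fixed lists, with the number tested beside each name. Blue points passed the gene test and grey points did not. Bars are medians, red where the list passed the preset-correlation test, which holds for 23 lists. The median ran from -0.78 for the interferon list to 2.18 for the erythrocyte list.

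All 8 tested erythrocyte genes rose, 7 of them with a log2 fold change of at least 1, and the median was 2.18 (adjusted p = 5.13e-09, and adjusted p = 0.0391 with an estimated correlation). Of 9 tested neutrophil genes 5 rose, 2 fell and 2 did not pass the test (median 0.35, adjusted p = 0.0157). The call was lost with an estimated correlation (adjusted p = 0.184 with an estimated correlation). The members that rose are calprotectin and granule genes. S100a9, the partner of S100a8, rose from 11.7 ± 1.06 to 31.5 ± 0.865 FPKM, and Ngp, a granule protein, from 0.113 ± 0.0686 to 2.23 ± 0.269. Mmp8, neutrophil collagenase, fell from 36.5 ± 0.895 to 29.5 ± 0.262 FPKM, and the chemokine receptor gene Cxcr1 also fell. The lymphocyte list did not pass (9 tested, 2 higher, 2 lower, adjusted p = 0.785). Within it Cd8a fell from 59.6 ± 3.10 to 31.7 ± 1.30 FPKM and Cd8b from 15.4 ± 0.117 to 11.6 ± 0.493, while Cd4 rose from 21.4 ± 0.673 to 33.0 ± 0.851. Other T cell genes of the list were far lower, with Cd3g at 1.16 and Lck at 1.29 FPKM in SCI. The Cd8a, Cd8b and Cd4 values therefore cannot be read as a shift between T cell types. Cd3e, a chain of the T cell receptor complex, rose from 0.287 ± 0.0782 to 0.756 ± 0.244 FPKM (adjusted p = 0.0363), and lost its call without any 1 of the SCI libraries (adjusted p from 0.0582 to 0.1). All 3 lists had the same counts adjusted over the list alone. Of 16 detected genes of bone marrow precursors, listed after these values were seen, 6 lay above every SCI library in every ES library and 2 below, beside 20.4% and 32.7% of all 17774 detected genes. Detection needed a mean of at least 0.2 FPKM in at least 1 group, and some of these genes reached it in only 1 group.

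Myelin genes rose together. Of 19 tested oligodendrocyte genes 18 rose and 1 fell, with a median of 0.55 (adjusted p = 8.42e-10, and adjusted p = 0.0391 with an estimated correlation). These counts also held adjusted over the list alone. Cnp, an enzyme of myelinating cells, rose 1.70-fold from 495 ± 5.44 to 839 ± 2.5 FPKM, and the galactolipid enzyme gene Ugt8 1.79-fold to 155 ± 0.734. The exception was Tf, transferrin, which fell from 1048 ± 15.7 to 691 ± 1.09 FPKM. Of 13 precursor genes 8 rose, 3 fell and 2 did not pass (median 0.59, adjusted p = 0.0106, and adjusted p = 0.0917 with an estimated correlation). With p-values adjusted over the list alone 8 rose and 4 fell. The transcription factor genes Olig1, Olig2 and Sox10 rose 1.81-fold, 1.67-fold and 1.63-fold, and Gpr17, a receptor of differentiating precursors, 2.10-fold to 42.3 ± 2.13 FPKM. The members that fell were C1ql1, Pdgfra, the growth factor receptor of precursors, and Bmp4. Of 21 cholesterol synthesis genes 11 rose and 3 fell (median 0.22, adjusted p = 0.00267, and adjusted p = 0.0605 with an estimated correlation), the same counts as adjusted over the list alone. Cyp51 rose 1.35-fold to 41.8 ± 0.335 FPKM, while Srebf2, the transcription factor that drives the pathway, Dhcr7 and Lss fell. Beside these groups, astrocyte, fibroblast, vessel and Schwann cell lists had negative medians in the same libraries.

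Neuronal and synaptic lists had positive medians. Of 17 pan-neuronal genes 11 rose and 6 did not pass (median 0.42, adjusted p = 6.41e-06, and adjusted p = 0.0601 with an estimated correlation). The number that rose was 13 adjusted over the list alone. Tubb3, a neuronal tubulin, rose 1.40-fold to 88.6 ± 1.83 FPKM, and the neurofilament gene Nefm 1.34-fold to 85.5 ± 1.70. Among those that did not pass, Eno2 stood at 34.7, 35.3 and 0.674 FPKM in ES replicates 1 to 3 and Map2 at 6.81, 18.5 and 5.86 in SCI replicates 1 to 3. Of 22 synaptic vesicle genes 13 rose and 1 fell (median 0.37, adjusted p = 5.25e-05, and adjusted p = 0.0605 with an estimated correlation). Vamp1 and Syn1, of vesicle fusion and clustering, rose 1.76-fold and 1.71-fold, to 72.2 ± 2.79 and 13 ± 0.571 FPKM. Of 17 glutamatergic genes 11 rose and 2 fell (median 0.31, adjusted p = 0.000476, and adjusted p = 0.0601 with an estimated correlation). The AMPA receptor subunit genes Gria2 and Gria3 rose 1.71-fold and 1.59-fold, while the receptor genes Grin2c and Grm5 fell. Of 20 GABA and glycine genes 6 rose and 2, Gabra2 and Gabbr1, fell (median 0.14, adjusted p = 0.0352, and adjusted p = 0.127 with an estimated correlation). Without SCI replicate 2 that list did not pass (adjusted p = 0.066). Glrb, the glycine receptor beta subunit, rose 1.74-fold to 22.4 ± 0.663 FPKM, and Gad1 and Gad2, which make GABA, rose 1.56-fold and 1.81-fold. Adjusted over the list alone the counts of the synaptic vesicle, glutamatergic and GABA lists were the same. Schwann cell and smooth muscle lists had negative medians in the same libraries (-0.69 and -0.51), as did genes of the meninges (-0.60).

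Motor neuron genes (7 tested, adjusted p = 0.700) and voltage-gated channel genes (22 tested, adjusted p = 0.844) did not pass as lists. Prph, peripherin, rose 1.69-fold to 24.1 ± 0.166 FPKM, while Ret and Chodl fell. Ache stood at 3.29 ± 0.591 against 2.13 ± 0.608 FPKM (adjusted p = 0.0561) and passed after quantile normalization (0.0232) and without SCI replicate 3 (0.0157). Hcn2, a pacemaker channel gene, rose 1.84-fold to 36.1 ± 0.3 FPKM, and the potassium channel gene Kcna2 fell from 10.9 ± 0.392 to 5.83 ± 0.234 FPKM. In these lists 1 and 2 genes rose and 2 and 4 fell. The counts adjusted over the list alone were 2 and 2 that rose and 2 and 3 that fell.

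Astrocyte genes fell. Of 14 tested 11 fell, 1 rose and 2 did not pass (median -0.48, adjusted p = 0.00228, and adjusted p = 0.0605 with an estimated correlation). Gfap, the astrocyte intermediate filament, fell from 2880 ± 10.7 to 1995 ± 2.27 FPKM, Aldh1l1 from 24.0 ± 0.881 to 10.4 ± 0.452, and the glutamate transporter gene Slc1a2 from 40.4 ± 2.40 to 18.4 ± 0.498. The member that rose was Glul, glutamine synthetase. Of 22 reactive astrocyte genes 15 fell, 3 rose and 4 did not pass (median -0.37, adjusted p = 0.0175, and adjusted p = 0.103 with an estimated correlation). Hspb1, a small heat shock protein, fell from 440 ± 6.18 to 307 ± 3.96 FPKM, and Vim from 2077 ± 28.4 to 1552 ± 14.8. Slc10a6, Cd14 and Emp1 rose. Of 12 ependymal and cilia genes 10 fell and 2 did not pass (median -0.44, adjusted p = 0.00107, and adjusted p = 0.0605 with an estimated correlation). Dnah11 and Drc1, of the axoneme, fell to 1.96 ± 0.0886 and 4.10 ± 0.407 FPKM from 3.39 ± 0.181 and 6.88 ± 0.521. Both astrocyte lists had the same counts adjusted over the list alone, and 11 ependymal genes fell.

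Microglia and macrophage lists had positive medians. Of 15 homeostatic microglia genes 11 rose, 2 fell and 2 did not pass (median 0.53, adjusted p = 5.25e-05, and adjusted p = 0.0601 with an estimated correlation). Csf1r, the receptor microglia need to survive, rose 1.70-fold to 178 ± 2.69 FPKM, and Aif1 1.43-fold to 124 ± 1.23. Olfml3 fell from 84.7 ± 2.78 to 36.6 ± 1.02 FPKM, and the transcription factor gene Sall1 also fell. Of 23 phagocytic macrophage and lysosome genes 16 rose and 4 fell (median 0.30, adjusted p = 3.79e-05, and adjusted p = 0.0601 with an estimated correlation). Spp1, osteopontin, rose 3.12-fold from 740 ± 11.3 to 2308 ± 21.0 FPKM, and the lysosomal protease genes Ctsd and Ctsl 1.62-fold and 1.45-fold. Fabp5, Abca1 and Apoe, of lipid handling, and Lgals3, a lectin gene, fell. Of 12 repair-associated macrophage genes 11 rose and 1, Clec10a, did not pass (median 0.36, adjusted p = 2.98e-06, and adjusted p = 0.0573 with an estimated correlation). Stab1 and Msr1, scavenger receptor genes, rose 2.58-fold and 2.12-fold, and Il1rn, the interleukin 1 receptor antagonist, 2.17-fold. Adjusted over the list alone 16 phagocytic genes rose and 5 fell, and the other 2 lists kept their counts. Globin genes rose in the same libraries.

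Interferon response genes fell, all 22 of 22 tested, with a median of -0.78 (adjusted p = 8.42e-10, and adjusted p = 0.0391 with an estimated correlation). The count was the same adjusted over the list alone. The antiviral GTPase genes Mx2 and Mx1 fell from 116 ± 2.17 to 47.6 ± 1.88 FPKM and from 79.3 ± 1.67 to 44.6 ± 0.546. Irf7, a transcription factor of the response, fell from 85.2 ± 2.37 to 42.5 ± 1.31 FPKM, and Ifi27 from 367 ± 7.40 to 194 ± 5.81. Ifit1, which the list does not hold, rose, while its family members Ifit2 and Ifit3, which the list holds, fell. The chemokine genes Cxcl13, Cxcl10 and Cxcl9, of which the last 2 are interferon-induced, fell to 1.97 ± 0.338, 24.2 ± 1.18 and 1.53 ± 0.414 FPKM from 11.05 ± 0.988, 43.6 ± 3.95 and 5.001 ± 0.719. As a list, cytokines and inflammatory enzymes did not pass (16 tested, 2 higher, 5 lower, adjusted p = 0.844). Its median of 0.02 and its mean of -0.18 differ in sign, and the median was -0.05 after rescaling to equal totals. Adjusted over the list alone 3 rose and 5 fell. Endothelial, smooth muscle and fibroblast lists also had negative medians in the same libraries (-0.41, -0.51 and -0.30).

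Of 11 genes of MHC class II presentation 5 rose and 6 did not pass (median 0.27, adjusted p = 0.00228, and adjusted p = 0.181 with an estimated correlation), the same counts as adjusted over the list alone. RT1-Bb rose 4.59-fold to 3.09 ± 0.308 FPKM, and Cd74, the invariant chain, and Ctss 1.25-fold and 1.26-fold. Complement genes split. Of 18 tested 9 rose and 7 fell, and the list did not pass (adjusted p = 0.110), with the same counts adjusted over the list alone. C1qb rose 1.55-fold to 1016 ± 18.6 FPKM, while the C1 protease gene C1r, the C1 inhibitor gene Serping1 and Cfb fell to 74.6 ± 1.23, 154 ± 2.23 and 8.57 ± 0.279 FPKM from 109 ± 1.27, 280 ± 3.76 and 22.8 ± 1.39.

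Vessel wall, scar and peripheral nerve sheath genes fell. Of 13 pericyte and smooth muscle genes 12 fell and 1, Higd1b, did not pass (median -0.51, adjusted p = 5.25e-05, and adjusted p = 0.0601 with an estimated correlation). Myh11, smooth muscle myosin, fell from 17.0 ± 0.542 to 5.36 ± 0.171 FPKM, and Vtn from 53.9 ± 1.60 to 21.6 ± 1.38. Of 20 fibroblast and scar genes 16 fell and 2, Col4a1 and Postn, rose (median -0.30, adjusted p = 0.000745, and adjusted p = 0.0601 with an estimated correlation). Fn1, fibronectin, fell from 157 ± 1.11 to 97.3 ± 0.359 FPKM, Lox, which crosslinks collagen, from 27.9 ± 0.628 to 12.2 ± 0.644, and Col3a1 from 509 ± 3.34 to 408 ± 1.18. Of 13 endothelial genes 8 fell and 5 did not pass (median -0.41, adjusted p = 0.00175, and adjusted p = 0.0605 with an estimated correlation), and Vwf fell from 31.1 ± 0.330 to 15.8 ± 0.488 FPKM. Of 12 Schwann cell genes 9 fell, 2 rose and 1 did not pass (median -0.69, adjusted p = 0.00866, and adjusted p = 0.0903 with an estimated correlation). Pmp22, a protein of peripheral myelin, fell from 299 ± 6.26 to 148 ± 0.393 FPKM, and Prx from 51.0 ± 0.395 to 16.6 ± 0.219. The members that rose were Sox10, also an oligodendrocyte gene, and Ngfr. Adjusted over the list alone 10 endothelial genes fell, and the other 3 lists kept their counts. Genes of the meninges, listed after these values were seen, had a median log2 fold change of -0.60 in the same libraries.

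Cell cycle genes rose, 22 of 24 tested, with a median of 0.59 (adjusted p = 8.60e-10, and adjusted p = 0.0601 with an estimated correlation), the same counts as adjusted over the list alone. Mki67, a marker of cycling cells, rose 2.12-fold to 7.61 ± 0.310 FPKM, Rrm2, a subunit of ribonucleotide reductase, 2.89-fold to 10.97 ± 1.10, and Top2a 1.77-fold to 10.1 ± 0.0180. Aurkb, a mitotic kinase, fell from 17.3 ± 0.338 to 4.56 ± 0.336 FPKM, and Tyms, thymidylate synthase, also fell. Erythrocyte genes, with a median of 2.18, rose in the same libraries. Of 13 mitochondrially encoded genes 10 rose and 3 did not pass (median 0.30, adjusted p = 5.25e-05, and adjusted p = 0.231 with an estimated correlation), the same counts as adjusted over the list alone. After quantile normalization that list's median was -0.01 and its call was lost (adjusted p = 0.69). Mt-atp6 rose 5.42-fold from 2814 ± 199 to 15258 ± 259 FPKM, and Mt-atp8, which overlaps it (MT 7758 to 7961 and 7919 to 8599), stood at 8604 ± 150 against 6499 ± 353. How reads were divided between these overlapping genes is not known, so the change of Mt-atp6 alone is uncertain. Mt-atp8 and Mt-co2 lost their calls after quantile normalization (adjusted p = 0.113 and 0.102).

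Of the lists on growth and repair, none of the following passed. Neurotrophic factors and receptors held 4 genes that rose and 10 that fell of 19 tested (adjusted p = 0.0901), and passed without ES replicate 3 (adjusted p = 0.0482). Ntrk2, the receptor of brain-derived neurotrophic factor, fell from 65.2 ± 1.58 to 37.3 ± 0.0533 FPKM, and Cntf from 34.4 ± 2.11 to 23.1 ± 0.466. Regeneration-associated genes held 10 that rose and 8 that fell of 23 (adjusted p = 0.159). Stmn4 and Gap43, of growing axons, rose 1.72-fold and 1.35-fold, to 231 ± 2.02 and 69.5 ± 1.74 FPKM. Axon growth inhibition held 7 that rose and 14 that fell of 27 (adjusted p = 0.159). Mag, of myelin, rose 1.5-fold to 475 ± 5.11 FPKM, while Nrp1 and Sema3a, a receptor and the semaphorin it binds, fell to 13.6 ± 0.0995 and 2.43 ± 0.121 FPKM from 27.9 ± 0.364 and 4.999 ± 0.241. Neural stem genes held 1 that rose and 7 that fell of 12 (adjusted p = 0.197), and Msi1 fell from 11.6 ± 0.533 to 7.497 ± 0.197 FPKM. Proteoglycan genes held 6 that rose and 3 that fell of 14 (adjusted p = 0.445). Ncan, neurocan, fell from 29.7 ± 0.413 to 15.5 ± 0.358 FPKM, and Bcan, brevican, rose 1.32-fold. When adjusted over the list alone, 15 axon growth inhibition genes fell, 2 neural stem genes rose and 5 proteoglycan genes fell, with no other difference in these 5 lists.

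Stress and housekeeping lists did not pass either. Hmox1, haem oxygenase 1, rose 2.80-fold from 101 ± 0.652 to 284 ± 4.74 FPKM within the heat shock and oxidative stress list (22 tested, 7 higher, 9 lower, adjusted p = 0.844). The immediate early list had 4 higher and 7 lower of 19 (adjusted p = 0.577), with Btg2 1.67-fold higher and Egr2 lower at 2.95 ± 0.284 against 5.91 ± 0.639 FPKM. The apoptosis list had 5 higher and 6 lower of 23 (adjusted p = 0.844), and Bcl2 fell from 1.15 ± 0.250 to 0.114 ± 0.0379 FPKM. The nuclear-encoded respiratory chain had 7 higher and 5 lower of 32 (adjusted p = 0.109), and passed after median centring (adjusted p = 0.0302). The ribosomal proteins had 10 higher and 7 lower of 31 (adjusted p = 0.252). Of 7 skeletal muscle genes 1, Myl1, rose (list adjusted p = 0.114), at 1.04 ± 0.306 against 0.262 ± 0.359 FPKM (adjusted p = 0.0380). Its call was lost without ES replicate 1 or 3 or SCI replicate 1 or 3 (adjusted p from 0.103 to 0.109) and with a pseudocount of 0.1 (adjusted p = 0.0596). The apoptosis and heat shock lists had negative medians (-0.03 and -0.08) and means (-0.05 and -0.03) with a test direction towards higher values, and the respiratory chain a median of 0.01 and a mean of -0.03. Under other scalings the medians of 4 of these lists changed sign, with values from -0.10 to 0.02 for apoptosis, -0.07 to 0.06 for the respiratory chain, -0.10 to 0.05 for ribosomal proteins and -0.02 to 0.39 for skeletal muscle. Adjusted over the list alone, 6 apoptosis genes rose, 8 ribosomal genes fell and 0 muscle genes passed, with the other counts the same.

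Among annotation terms, chromosome, splicing, lysosome and synaptic vesicle genes tended to be higher with stimulation, and matrix, antiviral and cilium genes lower. The centromeric region of chromosomes led the higher set, with 32 genes that rose and 3 that fell of 66 (adjusted p = 6.34e-05, and adjusted p = 0.542 with an estimated correlation). With an estimated correlation 0 terms passed. Chromosome segregation (28 and 7 of 61), the spliceosome (52 and 13 of 132), the lysosome (51 and 17 of 111) and the synaptic vesicle membrane (14 and 3 of 43) were also among them (adjusted p = 0.542 with an estimated correlation for each). The extracellular matrix held 25 genes that rose and 85 that fell of 152, and defense response to virus 5 and 42 of 73 (adjusted p = 0.00603 each, and adjusted p = 0.542 with an estimated correlation). Cell-matrix adhesion (1 and 19 of 32), basement membrane (12 and 39 of 61) and cilium movement (0 and 13 of 21) were in the lower set (adjusted p = 0.542 with an estimated correlation, or 0.543 for basement membrane). The terms came from the annotation columns of the tables and were tested in the same way, and 57 of 1620 passed, 41 towards higher and 16 towards lower values in ES.

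Transcripts of Hbb and Igfbp3 were among the 3 higher ones with the smallest p-values. The Igfbp3 transcript ENSRNOT00000088355 (chromosome 14, 87457647 to 87465374) rose from 26.1 ± 0.533 to 133 ± 2.00 FPKM (adjusted p = 2.30e-06). Among the lower ones, the St3gal5 transcript ENSRNOT00000078793 (chromosome 4, 99937711 to 99999902), of ganglioside synthesis, was listed at 0 in the 3 ES libraries and stood at 57.8 ± 4.77 FPKM in SCI (adjusted p = 2.30e-06). Transcripts of Ptgds, prostaglandin D synthase, and of Clu, clusterin, fell from 4328 ± 51.7 to 1543 ± 17.8 FPKM and from 2749 ± 53.6 to 903 ± 8.49. Over all transcripts 6213 of 19223 differed, 2463 higher and 3750 lower in ES. The split of transcript calls was 2904 higher and 2924 lower after quantile normalization, 2974 and 3078 after median centring, and 1857 and 4760 after rescaling to equal totals. The authors' deposited table marked 1162 transcripts as significant, 409 up and 753 down, of which 814 were called here.

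Nlgn3, a synaptic adhesion gene on chromosome X, had close gene values, 11.9 in ES and 11.7 FPKM in SCI, and a different main transcript. ENSRNOT00000005077 (8 exons) held 68.8 ± 2.71% of the gene's transcript FPKM in ES and 0.293 ± 0.368% in SCI (SD, n = 3), and ENSRNOT00000005102 (7 exons) 26.8 ± 1.13% and 91.1 ± 0.897% (adjusted p = 4.13e-09). In Mbp, myelin basic protein, ENSRNOT00000058296 rose from 1.04 ± 0.148% to 2.74 ± 0.257% (adjusted p = 1.30e-08), and ENSRNOT00000022280, the most abundant one, stood at 60.6 ± 0.521% in SCI and 58.1 ± 0.732% in ES. Ptcd3, of mitochondrial translation, and the small GTPase gene Arl2 were also among the 5 genes with the smallest p-values. The Ptcd3 transcript ENSRNOT00000078991 held 4.69 ± 0.323% in ES and 28.7 ± 2.85% in SCI. The Arl2 transcript ENSRNOT00000093048 was listed at 0 in ES and stood at 6.08 ± 1.90 FPKM in SCI. The division of a gene's FPKM among its transcripts differed for 228 of 2589 genes with at least 2 transcripts past the filter, and for 115 with the replicate number as a block. The FPKM of transcripts that share most of their exons are estimates, and the tables give no error for them.

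**Figure D3:**
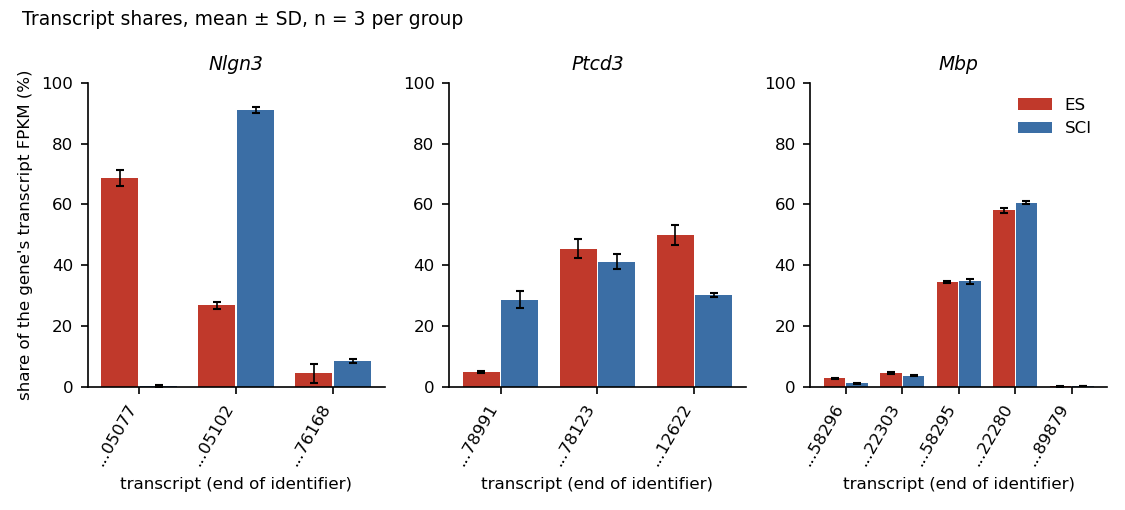
Share of the gene's transcript FPKM (percent) held by each transcript of Nlgn3, Ptcd3 and Mbp, as mean with SD over 3 ES (red) and 3 SCI (blue) libraries. In Nlgn3 a different transcript leads in each group, and in Mbp the same one leads in both. In Ptcd3 the ES shares of ENSRNOT00000012622 (49.8 ± 3.33%) and ENSRNOT00000078123 (45.5 ± 3.15%) lie too close to name a leader.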

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

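The 1.5-fold minimum, the leaving out of irregular genes, and median centring and equal totals for lists were chosen after the values were seen. Of the 7088 gene calls 424 reached a 2-fold change and 1708 a 1.5-fold change on the log2(FPKM + 1) scale, and of the 6213 transcript calls 599 and 1983, by the construction of these limits. The other alternatives kept the gene count between 5916 and 8390 and the transcript count between 4543 and 7807. With an estimated correlation 3 of 23 lists (2 towards higher, 1 towards lower values) and 0 of 57 terms passed, and with fry, which does not compare a list with other genes, 35 lists passed. The authors' mark with a q-value under 0.05 as well left 985 genes and 581 transcripts. Leaving out 1 library gave 5916 to 6416 genes, 4710 to 5249 transcripts, 22 to 24 lists, 47 to 57 terms and 163 to 193 usage genes. Nothing in the labels says that the replicate numbers pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.0264, -0.0261 and -0.0292, and no library correlated best with its own number. The highest values were 0.0760 (ES 1 with SCI 2), 0.0783 (ES 2 with SCI 3) and 0.0796 (ES 3 with SCI 1). Such small correlations cannot settle whether animals were paired. With the replicate number as a block there were 6317 gene calls, 4543 transcript calls, 23 lists, 56 terms and 115 usage genes against 228, and among named genes Cd3e and Myl1 lost their calls (adjusted p = 0.0596 and 0.0905). Under fry the direction of the lymphocyte, cytokine and apoptosis lists, not called by camera, was towards lower values, with medians of 0.00898, 0.0177 and -0.0297. Over the 10 alternatives run for single genes, named genes called in the main test kept their call 1625 times, lost it 12 times and reversed 0 times, and those not called stayed so 34 times and gained a call 6 times. Over 16 alternatives the 23 called lists kept their call 346 times, lost it 22 times and reversed 0 times. The 16 others stayed uncalled 242 times and gained a call 14 times, 3 of them, under fry, against the main direction. Under the 3 other scalings the medians of called lists kept their sign except for mitochondrially encoded genes, and 9 of the 16 others changed sign under at least 1. The cause was not tested. At 0.3 to 1 FPKM the coefficient of variation between libraries was 22.6% in ES and 24.6% in SCI, which limits calls of low genes.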

Other observations

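The test that sets astrocyte against oligodendrocyte genes and the counts over other splits of the samples were chosen only after the result was seen, and the genes named in the first 2 paragraphs were chosen after their values were seen. Marker genes of the meninges, the membranes around the cord, were mostly lower with stimulation. Of 25 such genes listed, none of them in a list used above, 24 were tested, 21 fell and 1 rose. Slc47a1, an organic cation exporter, fell from 21.8 ± 0.681 to 6.41 ± 0.869 FPKM (SD, n = 3), and the transcription factor genes Zic1 and Foxc1 from 44.0 ± 3.11 to 19.4 ± 0.405 and from 15.3 ± 0.659 to 8.61 ± 0.217. Mgp, an inhibitor of calcification, fell from 574 ± 1.07 to 384 ± 9.16 FPKM, and Islr rose 1.71-fold. Of 22 Hox genes tested of 35 in the table, which mark the position along the cord, 7 fell and 1 rose, with a median log2 fold change of -0.30. Over all 15750 genes tested 4341 fell and 2747 rose. Hoxc6 fell from 17.3 ± 1.35 to 10.2 ± 0.892 FPKM, and Hoxb7 rose from 10.7 ± 0.532 to 12.8 ± 0.162.

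Some genes were listed at 0 in all libraries of 1 group and at 1 FPKM or more in all libraries of the other. There were 6 such genes listed at 0 in SCI and 5 listed at 0 in ES. RatNP-3b, a defensin gene like Defa5 and Np4, stood at 3.12, 4.65 and 3.03 FPKM in ES replicates 1 to 3, and LOC103690108 (chromosome 20, 3791407 to 3794027) at 42.5, 32.0 and 38.8. Tctn3, of the cilium transition zone, stood at 2.93, 3.06 and 2.88 FPKM in SCI replicates 1 to 3 and was listed at 0 in ES. AC134224, a long intergenic noncoding RNA gene (ENSRNOG00000062158, chromosome 1, 221158098 to 221158792), stood at 577 ± 24.3 FPKM in ES against 39.6 ± 3.53 in SCI, 14.6-fold. LOC100134871, a gene whose coordinates (chromosome 1, 168957460 to 168958836) lie within those of Hbb-bs, rose 5.25-fold to 554 ± 3.79 FPKM. The coefficient of variation of Hbb between libraries was 1.22% in ES and 1.501% in SCI, beside its 6.77-fold difference between groups.

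The first pattern weighed is that fibroblast, smooth muscle, vessel and Schwann cell genes fell while myelin and neuron genes rose. A candidate explanation is that the ES tissue held less meninges, and the median log2 fold change of the meningeal genes, at -0.60 (95% bootstrap interval over genes -0.77 to -0.31), went with it. Less meninges and nerve root around an otherwise like cord would raise astrocyte and oligodendrocyte genes alike. The astrocyte median lay below the oligodendrocyte median by a difference of -1.03 (interval over genes -1.49 to -0.58). This contrast was chosen after the medians of these lists were known. It therefore restates them and does not weigh for or against less meninges and nerve root as the cause. For tissue from another level of the cord, the log2 fold changes of 22 Hox genes did not run with their paralogue number. Across these genes, which are not independent replicates, Spearman rho was -0.00796 (interval -0.395 to 0.381, permutation p = 0.973, Pearson r 0.0357). A shift that changes only some Hox genes need not give such a trend, so another level is not excluded. Of these Hox genes 7 fell and 1 rose, beside 4341 that fell and 2747 that rose of all 15750 genes tested. Of 42 genes of anterior/posterior pattern specification 20 fell and 1 rose (camera adjusted p = 0.0109, and 0.542 with an estimated correlation). How many of these 42 are Hox genes was not counted, so the term is not a separate line of evidence. An effect of stimulation on scar, vessel or nerve sheath tissue stays open beside the dissection, because the labels do not say how the tissue was taken.

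The second pattern is that red cell genes and 5 of 9 neutrophil genes rose. Bone marrow cells in the ES tissue, as might come from bone at dissection, would bring genes of marrow precursors, and 37.5% of the 16 detected ones had all ES libraries above all SCI libraries, against 20.4% of 17774 detected genes, where chance gives 5%. Mpo, Elane, Ctsg and Fcnb were among the 6 that did, with Fcnb at 9.41 FPKM in ES and 1.97 in SCI, and Klf1 and Epor of red cell precursors were not. Detection needed a mean of at least 0.2 FPKM in at least 1 group. Mpo, Elane and Ctsg, at 0.313, 0.304 and 0.472 FPKM in ES, passed it only through ES. Prtn3 and Epb42 passed it only through SCI. Such genes lean towards the group that let them in, so the share cannot weigh for marrow. More circulating blood would bring lymphocyte genes, and 23.5% of 17 detected ones were above, with 5 below and the most abundant, Cd37, at 38.5 FPKM in ES and 34.2 in SCI. Of the 29 and 28 genes listed 7 and 6 also stand in lists used above and 3 and 7 reached 1 FPKM in SCI, and with so few detected genes marrow, blood and an effect of stimulation on bleeding or granulocyte entry cannot be told apart.

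The third pattern is that libraries of 1 group lay more than 2-fold apart for 131 of 7471 genes at 10 FPKM or more, beside a median coefficient of variation of 2.81% and 3.41% at 30 to 100 FPKM. Eno2 stood at 34.7, 35.3 and 0.674 FPKM in ES replicates 1 to 3, and Ndufa1 at 100.1 and 170 and listed at 0. Several transcript models per gene were argued against, with an odds ratio of 0.877 for having 2 or more transcripts (interval 0.576 to 1.31, Fisher's exact p = 0.562). Reads divided differently between overlapping gene models could play a part, since 32.1% of these genes overlapped another gene against 21.7% of the rest (odds ratio 1.71, interval 1.15 to 2.499, Fisher's exact p = 0.00728), and this stays open because the interval holds both a weak and a strong link. Overlap was counted on either strand, so it takes in neighbours on the other strand, whose reads stranded libraries can keep apart. Division of reads between copies at separate positions was not tested, and neither was any biological explanation.

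3 libraries against 3 make 10 splits, which cannot give a share under 0.05. The real split was the 1 with the most calls in each test. It gave 7088 genes where the highest other split gave 5, 6213 transcripts against 16, 23 lists against 12, 57 terms against 5 and 228 usage genes against 17. Every other split mixes ES and SCI libraries, so fewer calls there follow from any difference between ES and SCI libraries, whatever its cause.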
